A study of Homo sapiens with 4 samples.

How the data were processed

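Gene expression was compared between HEK293T cells transfected with plasmids expressing a siRNA against CHD6 and the same cells expressing a control siRNA. Per the labels' protocols, total RNA was taken 48 h after transfection, and 200 ng were amplified with an oligo dT-T7 primer and labelled with cyanine CTP for Agilent 2-colour arrays. Each of the 4 arrays was a direct hybridisation of a CHD6 siRNA sample against a control siRNA sample, labelled with Cy3 and Hy5. Per the labels, the CHD6 siRNA sample carried Cy3 on replicates 1 and 3 and Hy5 on replicates 2 and 4, so 2 arrays had each dye orientation. The labels do not say whether the 4 replicates came from separate cultures, so p-values measure the spread between these arrays, which may be technical.

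The deposited values were log ratios of both channels of each array, 1 column per array, taken here as log2. They covered 45220 features, were rounded to 2 decimals and held 0 missing values. The scale, centring and direction of the deposited columns are not given in the sources used here, nor are the scanner software, the background correction and the normalization. Column means were 0 to within rounding, and column medians were -0.02, 0.03, -0.02 and 0.02 for replicates 1 to 4. The base was taken as 2 because 1 SD of a column would then be a 1.36-fold to 1.43-fold ratio, against 2.75-fold to 3.27-fold under base 10. Channel intensities, spot backgrounds and flags were not used here, so signal over background is unknown, control spots could not be removed, and the number of arrays limits the precision. No column of values was left out (0 unused columns).

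The direction of the ratios needed a decision that departed from a rule fixed before the data were examined. That rule turned the columns by dye if arrays of opposite dye correlated clearly below 0, which they did (Pearson r from -0.84 to -0.68 across features). The columns were instead used as deposited and read as CHD6 siRNA over control siRNA. The basis was that the titles of all 4 arrays name the siRNA first, and that 1 of the 3 CHD6 features was below 0 in all 4 columns. This direction is called likely, not settled. It was chosen after the data were seen, including the CHD6 values and the shift of the p53 target list, so neither is an independent check of it. Values with the arrays turned by dye are given for CHD6, the called genes and the called lists, and as a range for the other named genes.

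Features were named through the platform's probe-gene table, updated by Entrez gene identifier to a RefSeq gene table (31291 features matched). Of the features, 31332 named 1 gene, 93 named several genes and 13795 were unnamed here. The features naming 1 gene were averaged per gene, which gave 18334 genes, 7759 of them with several features. Genes were tested with limma 3.58.1 in R 4.3.3. The model set before the data were examined had an intercept alone, with empirical Bayes moderation (eBayes) and Benjamini-Hochberg adjustment over all genes at 0.05. A fit with dye orientation as a further coefficient was also fixed at that time, as a second choice. It gives the same mean log ratio for a gene but takes the dye difference out of the residual spread. Adjusted p-values are limma's. With 4 arrays, an exact sign-flip test cannot give a two-sided p below 0.125.

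In all, 28 gene lists were fixed before the data were examined. They covered CHD and other chromatin remodelers, polycomb, trithorax and HOX genes, histones, cell cycle, DNA repair, stress and signalling responses, metabolism, ribosomes, nuclear import and polymerase subunits, RNA interference, neuronal genes and 3 sets of markers of other cell types. Lists were tested against all other genes with camera at a preset correlation of 0.01, with an estimated correlation as an alternative. fry was run beside it; it tests whether the members of a list move 1 way on balance, not whether they differ from other genes. The shift of a list on an array is the mean log ratio of its members minus that of all other genes.

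Genes were named by a rule fixed at the same time. It took CHD6, and per direction the 10 genes with the largest change among those past the threshold with 1 sign on all 4 arrays, filled up by the smallest p-values where fewer passed. For each list past the threshold it took up to 4 called members, or the 2 members with the smallest p where none was called. The rule was applied to both fits. Uncharacterised loci were skipped. Other genes, all features and the dye examples were chosen after their values were seen.

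Both fits were tested on simulated data for this comparison over 18334 genes, with the measured dye coefficients kept and 100 genes changed by 0.5 and 100 by 1 (log2). The intercept fit recovered 0% of either size, with 0 false calls. The fit with a dye coefficient was tested with true spreads drawn in 2 ways. With spreads drawn from limma's fitted prior it recovered 81% of the changes of 0.5 and 100% of those of 1, and 11 of its 192 calls were false (5.73%). With each gene's own moderated spread it recovered 100% of both sizes, and 27 of its 227 calls were false (11.9%), above the 5% aimed for. The second way of drawing was the first tried, and the first was added after its false calls were seen. Both sizes of change were simulated at once, and the adjustment is looser when many genes change. The recovered shares therefore need not hold where few genes change. In the measured data SUMF1 (0.61) and GDF15 (0.78) did not pass this fit (limma adjusted p = 0.0539 and 0.0887). Among the unchanged lists, camera called at most 1. The noise was drawn independently for each gene, so this does not test lists whose members are correlated. On the measured data, 2 lists were called for replicates 1 and 2 against 3 and 4, which hold no treatment difference. Replicates 1 and 4 against 2 and 3, likewise without one, also gave 2.

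The alternatives tried were single features, medians per gene, centring, scaling, quantile normalization, robust or no moderation, array weights, a fold filter of 1.5, a threshold of 0.1, each dye orientation alone, and leaving out each replicate. Scaling used normalizeMedianAbsValues on centred columns in place of the planned normalizeBetweenArrays call, which gave undefined values. Array weights were estimated gene by gene because the REML method did not converge. Turning the arrays by dye, single features with the dye coefficient, and all alternatives to the dye fit were chosen after seeing the data. Plots were drawn with matplotlib 3.10.9.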

Results

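The series measured transcripts in HEK293T cells, a human embryonic kidney line that carries the SV40 large T antigen, after RNA interference against CHD6. CHD6 is an ATP-dependent chromatin remodeler of the chromodomain helicase family. The comparison asked which transcripts differed between cells expressing a CHD6 siRNA and cells expressing a control siRNA at 48 h. There was 1 group of 4 arrays, each a direct comparison of both conditions, with 45220 features per array. Log ratios are given as CHD6 siRNA over control, a likely direction, and as log2, an assumed base.

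CHD6 itself was below control on all 4 arrays, mainly at 1 of its 3 features. Feature 27564 had a log ratio of -1.15 ± 0.24 (SD, n = 4), or 45.0% of control. Its values were -1.13, -1.21, -0.85 and -1.42 on replicates 1 to 4. It ranked 5 from the lowest among all 45220 features by mean as deposited, and would rank 10597 with the arrays turned by dye. Feature 1672, annotated to the same transcript, was at -0.02 ± 0.06 (SD, n = 4), and feature 36130 at -0.17 ± 0.30 (SD, n = 4), or -0.027 without replicate 4. The mean over the 3 features was -0.45 ± 0.15 (SD, n = 4), and taking their median instead gave -0.20.

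Feature 27564 passed the test once dye was in the model (limma adjusted p = 0.0339), but not with the intercept alone (adjusted p = 1). Its difference was larger than its spread between arrays in that fit too (limma unadjusted p = 0.000252). What it did not pass there was the adjustment over all features. The gene mean did not pass either test (adjusted p = 1 and, with the dye coefficient, 0.134). If the arrays were turned by dye, feature 27564 would be at -0.16 and the gene mean at -0.10. The standard error of the feature would be 0.67 with no dye term and 0.086 with dye orientation in the fit.

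**Figure D1:**
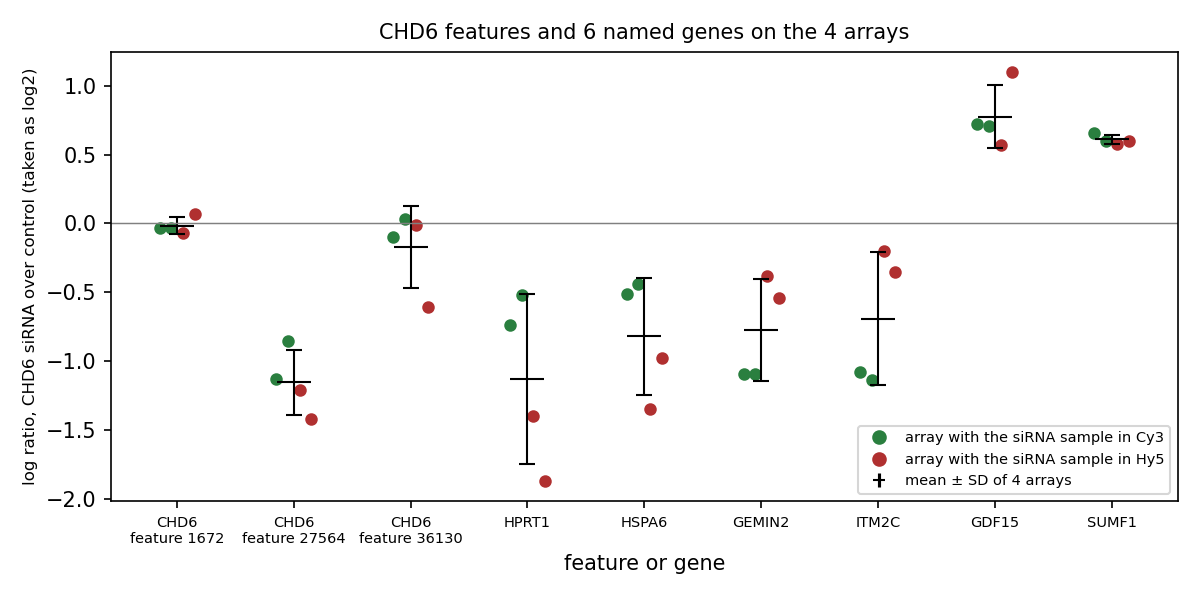
Log ratios of CHD6 siRNA over control (y axis, taken as log2) for 3 CHD6 features and 6 named genes (x axis), 1 point per array, coloured by the dye of the siRNA sample, with the mean and SD of 4 arrays. CHD6 feature 27564 and HPRT1 lie below 0 on all 4 arrays, at means of -1.15 and -1.13.

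Across the transcriptome, no gene passed the test with the intercept alone. limma called 0 of 18334 genes (smallest adjusted p = 1), with 242 genes at an unadjusted p under 0.05 where chance alone gives 916.7. That fit also recovered 0% of simulated changes of 1 (log2), because dye differences enter its spread, so its count of 0 does not show that genes were unaltered. With the dye coefficient it called 4 genes, all lower in CHD6 siRNA cells, and 1717 genes had an unadjusted p under 0.05. The 4 were HPRT1, GEMIN2, HSPA6 and ITM2C. The count of 4 does not show how many genes changed, since the simulated recovery need not hold where few do. Each of the 4 calls was lost when any 1 replicate was left out, and without moderation none of the 4 passed. Leaving out 1 replicate leaves 1 array in 1 orientation, and without moderation each spread rests on 4 arrays alone. Both fits have less power and the calls lay near the threshold. Their loss therefore does not tell a fragile call from a lack of power.

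HPRT1, the purine salvage enzyme that recycles hypoxanthine and guanine, had the largest decrease of the 4, at -1.13 ± 0.62 (SD, n = 4; adjusted p = 0.0375 with the dye coefficient). All 10 of its features were low, with means from -1.20 to -1.03, and it stood at 45.7% of control, close to the value of the lowest CHD6 feature. These features are annotated to 1 transcript and may carry 1 probe sequence, so they may not be separate measurements. HPRT1 was at -0.74 and -0.52 on the arrays with the siRNA sample in Cy3 and at -1.40 and -1.87 on the others. HSPA6, a stress-inducible member of the HSP70 chaperone family, was at -0.82 ± 0.43 (SD, n = 4; adjusted p = 0.0436). GEMIN2, a subunit of the SMN complex that assembles spliceosomal ribonucleoproteins, was at -0.78 ± 0.37 (SD, n = 4; adjusted p = 0.0375). ITM2C, an integral membrane protein of the BRICHOS family, was at -0.69 ± 0.48 (SD, n = 4, adjusted p = 0.0436). These 3 genes differed with dye orientation too. With the siRNA sample in Cy3, HSPA6 was at -0.51 and -0.44, GEMIN2 at -1.09 and -1.09, and ITM2C at -1.08 and -1.135. With it in Hy5, HSPA6 was at -1.35 and -0.98, GEMIN2 at -0.38 and -0.54, and ITM2C at -0.20 and -0.355. Turned by dye, HPRT1, HSPA6, GEMIN2 and ITM2C would be at -0.50, -0.35, 0.32 and 0.42, none past the threshold with the intercept alone. With dye orientation in the fit, the turned difference is the dye coefficient, and all 4 would pass. Their limma adjusted p-values were then 0.00302, 0.00922, 0.00640 and 0.00173, in that order, with GEMIN2 and ITM2C higher. In that fit 8219 of all 18334 genes would pass, so passing does not single out these 4.

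Other genes low on all 4 arrays did not pass either test. The nearest were MYCBP, a MYC-binding protein (-0.65, adjusted p = 0.0539 with the dye coefficient), and IARS2, the mitochondrial isoleucyl-tRNA synthetase (-0.73, adjusted p = 0.0545). SLC66A3 (-0.63), DNAAF4 (-0.68), BNIP2 (-0.74, but -0.43 without replicate 4), GLCE (-0.57), RIMKLA (-0.54), RNF4BP (-0.48), KICS2 (-0.47), PPCS (-0.46) and PXYLP1 (-0.46) had adjusted p-values from 0.0887 to 0.120. BNIP2 was at -0.06 and -0.15 with the siRNA sample in Cy3 and at -1.09 and -1.65 in the other orientation. The 2 features of RIMKLA had means of -0.74 and -0.34. ATR, the kinase that signals replication stress, lay in the same range of adjusted p (0.117), and its 4 values from -0.49 to -0.39 lay close together (mean -0.44, SD 0.04).

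Genes high on all 4 arrays did not pass either test. SUMF1, which encodes the enzyme that activates sulfatases, was at 0.61 ± 0.03 (SD, n = 4; adjusted p = 0.0539 with the dye coefficient). GDF15, a stress-induced cytokine of the TGF-beta superfamily, was at 0.78 ± 0.23 (SD, n = 4; adjusted p = 0.0887), a 1.71-fold ratio. NEDD4, a ubiquitin ligase, was at 0.55 (adjusted p = 0.0972). GBE1, the glycogen branching enzyme (0.55), RELL1 (0.52), STMND1 (0.50), GHITM (0.49), GALNT14 (0.49), TCEAL7 (0.48), TTPAL (0.47), EMILIN2 (0.45), CCN1 (0.43) and REG1A (0.42) had adjusted p-values from 0.117 to 0.133. The 4 features of CCN1 differed, with means from -0.035 to 0.635. Turned by dye, the 36 named genes other than CHD6 would lie between -0.63 and 0.42, and 0 would pass with the intercept alone (smallest adjusted p = 0.109). With dye orientation in the fit, the 4 genes called above would pass, as would BNIP2, MYCBP, KICS2, RNF4BP, GHITM, TCEAL7 and GALNT14. The smallest limma adjusted p was then 0.00124 (BNIP2), and the other named genes would not pass. Over all genes, 8219 of 18334 would pass in that fit. In all, 653 genes (3.56%) were above 0 and 641 (3.50%) below 0 on all 4 arrays, less than the 6.25% each way that independent signs give by chance. Turned by dye, the counts would be 5744 (31.3%) and 3912 (21.3%).

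Of the 28 gene lists, 4 were higher in CHD6 siRNA cells by camera at the preset correlation and 0 were lower. None of the 4 passed with an estimated correlation. That form of camera takes its degrees of freedom from the few arrays, the preset form from the genes, so calls are hard to reach. For p53 and NF-kappaB targets the estimates (-0.033 and -0.017) were below the preset 0.01. Correlation between their members is therefore not what removed these calls. For histone genes and ribosomal proteins the estimates were higher (0.155 and 0.174). By fry, which tests a list against no change and not against other genes, 0 lists passed. p53 target genes had the smallest p (adjusted p = 4.15e-05; adjusted p = 0.352 with an estimated correlation; 0.0911 by fry). Of 26 measured members, 23 had a mean above 0, and the list lay above the other genes on each array, by 0.16, 0.09, 0.18 and 0.21 on replicates 1 to 4. No member was called over all genes. Adjusted over the list alone, 1 passed with the intercept alone, GDF15 (adjusted p = 0.0311), and 4 with the dye coefficient, all higher. These were GDF15, FAS, the death receptor (0.30 ± 0.18, SD, n = 4), the cell cycle inhibitor CDKN1A (0.36 ± 0.53, SD, n = 4) and MDM2, the p53 ubiquitin ligase (0.30 ± 0.54, SD, n = 4). CDKN1A was below 0 on replicates 1 and 3 and at 0.17 without replicate 4. MDM2 was below 0 on replicate 4 and at 0.12 without replicate 3. Turned by dye, the p53 list would lean lower (adjusted p = 0.869).

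NF-kappaB targets and inflammatory cytokines also lay above the other genes on each array, by 0.07, 0.05, 0.10 and 0.09 (adjusted p = 0.00392; adjusted p = 0.411 with an estimated correlation). Of 25 members, 21 had a mean above 0 and 8 were above 0 on all 4 arrays. Adjusted over the list alone, 0 passed with the intercept alone and 1 with the dye coefficient, the NF-kappaB subunit RELB (0.60 ± 0.35, SD, n = 4). The chemokine CXCL3 was at 0.19 ± 0.03 (SD, n = 4) and did not pass. The call was lost without replicate 2 (adjusted p = 0.0522) or replicate 3 (adjusted p = 0.0723), and turned by dye the list would lean lower (adjusted p = 0.873).

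Histone genes and cytosolic ribosomal proteins were called higher, but moved with dye orientation. Histone genes (33 measured; adjusted p = 0.000105; adjusted p = 0.704 with an estimated correlation) were shifted by 0.22 and 0.25 on the arrays with the siRNA sample in Hy5 and by 0.04 and -0.08 on the others. Of these, 27 had a mean above 0. The linker histone gene H1-4 was at 0.27 ± 0.13 (SD, n = 4) and H3-3B, which encodes histone H3.3, at -0.28 ± 0.14 (SD, n = 4). Ribosomal proteins (47 measured; adjusted p = 0.0126; adjusted p = 0.759 with an estimated correlation) were shifted by 0.11 and 0.44 in the Hy5 orientation and by -0.06 and -0.08 in the other. RPS7 (0.16 ± 0.15, SD, n = 4) and RPL14 (0.15 ± 0.14, SD, n = 4) had the smallest p of that list; RPL14 was at -0.013 on replicate 2 and at 0.094 without replicate 3. No member of either list passed, over all genes or adjusted over the list alone. The histone call was lost without replicate 2 (adjusted p = 0.104), and the ribosomal list leaned lower without replicate 4 (adjusted p = 0.768). Turned by dye, neither would pass (adjusted p = 0.555 and 0.267).

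**Figure D2:**
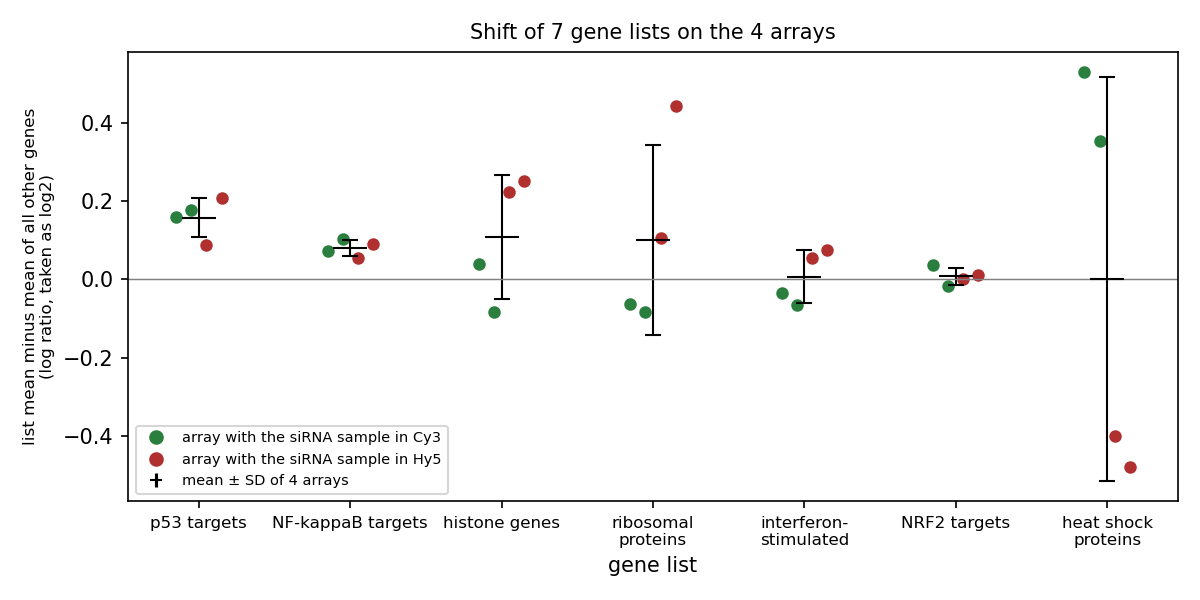
Mean log ratio of 7 gene lists minus that of all other genes (y axis, taken as log2; x axis, the lists), 1 point per array, coloured by the dye of the siRNA sample, with the mean and SD of 4 arrays. The p53 and NF-kappaB points lie above 0 on all 4 arrays, while the heat shock points split by dye, from 0.53 to -0.48.

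The other 24 lists did not pass. CHD family remodelers other than CHD6 (median -0.06, adjusted p = 0.637) and other remodeler subunits (median -0.03, adjusted p = 0.720) showed no call. Of the 9 CHD relatives, 1, CHD5, had 1 sign on all 4 arrays (0.07 ± 0.08, SD, n = 4). Interferon-stimulated genes, which respond to double-stranded RNA, had a median of 0.01 (adjusted p = 0.774), and NRF2 target and antioxidant genes a median of 0.00083 (adjusted p = 0.910). YAP/TEAD targets (adjusted p = 0.0779), neuronal genes and REST targets (adjusted p = 0.0961) and unfolded protein response genes (adjusted p = 0.165) leaned higher. So did TGF-beta targets and matrix genes (0.219), immediate early genes (0.257), respiratory chain subunits (0.264) and WNT targets (0.496).

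The nuclear import and polymerase list (adjusted p = 0.189), hypoxia and glycolysis (0.264), DNA repair (0.264), autophagy and lysosome genes (0.489), cholesterol and fatty acid synthesis (0.496), S phase genes (0.496), polycomb, trithorax and HOX genes (0.496) and the RNA interference pathway (0.662) leaned lower. Mitosis genes had adjusted p = 0.978, with a median of 0.0075 and a mean of -0.0068. Heat shock proteins had adjusted p = 0.794, leaning lower in the test with a median of -0.0046 and a mean of 0.00048. WNT targets and fibroblast and keratinocyte markers had medians below 0 (-0.0017 and -0.0025) and means above 0 (0.03 and 0.0097). Markers of immune cells (adjusted p = 0.496), of erythroid cells and serum (0.496) and of fibroblasts and keratinocytes (0.647) were not called.

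Most of the variation in the columns followed the dye. Arrays of the same dye orientation correlated at 0.80 and 0.79 across features, and arrays of opposite orientation at -0.84 to -0.68; genes are not independent replicates. limma called the dye coefficient itself for 8219 of 18334 genes, 4927 of them above 0 and 3292 below. Its spread over genes was 0.38 (SD), against 0.12 for the mean log ratio. Contrasts of arrays that hold no treatment difference had spreads of 0.11 (replicates 1 and 4 against 2 and 3) and 0.08 (replicates 1 and 2 against 3 and 4), the first close to that of the mean log ratio. The dye component repeated between pairs of arrays at r = 0.856 across genes, and the mean log ratio at 0.396 (replicates 1 and 2 against 3 and 4) and 0.0845 (replicates 1 and 4 against 2 and 3). ZCRB1, an RNA-binding protein of the minor spliceosome, had the largest, at -2.89, with log ratios of 2.50 and 3.01 in 1 orientation and -2.88 and -3.17 in the other. ITM2B (-2.45) and PABPC3 (-2.34) were also among the lowest, and C15orf62 (1.91), NSG2 (1.78) and FGF3 (1.31) among the highest. Heat shock proteins were the only list called on this coefficient (median -0.35, adjusted p = 0.0102). Under the reading in which the columns are turned by dye, these would be treatment differences, with 7700 genes called, 4675 higher and 3025 lower.

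**Figure D3:**
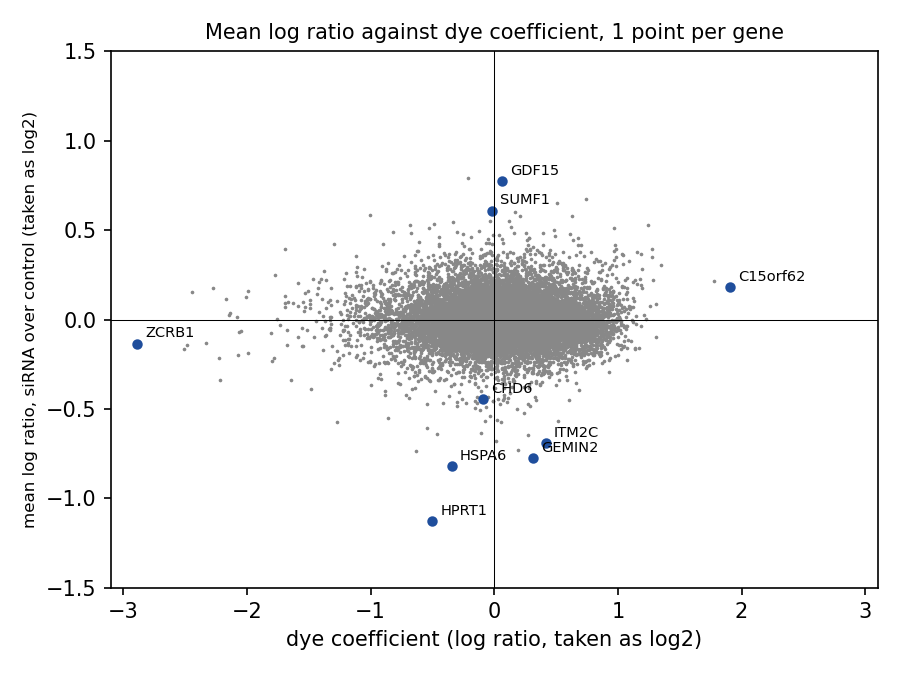
Mean log ratio of CHD6 siRNA over control (y axis) against the dye coefficient (x axis), both taken as log2, 1 grey point per gene, with 9 genes named in blue. The points spread further along the dye axis (SD 0.38) than along the axis of the mean log ratio (SD 0.12).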

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

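All tests of explanations in this part were chosen after the results were seen. A gap rule for 1 array far from the other 3 was applied to 68 groups of 4 values, where chance gives about 3.4; 5 were found. CXCL3 was at 0.135 on replicate 4 against 0.20 to 0.21 on the others. H1-4 was at 0.47 on replicate 2 against 0.19 to 0.22. RPS7 was at -0.067 on replicate 1 against 0.21 to 0.27. The shift of the other remodeler subunits was -0.046 on replicate 3 against -0.0023 to 0.0065. The nuclear import and polymerase list was shifted by 0.046 on replicate 1 and by -0.065 to -0.059 on the others. Outside the named genes, feature 25114, which is unnamed here, was at 1.18 (0.95 to 1.48 on the 4 arrays; adjusted p = 0.0339 with the dye coefficient), the highest of the features called in that fit.

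The first pattern is that arrays of opposite dye ran against each other. A candidate explanation is dye bias tied to the probe: the dye component repeated between array pairs at r = 0.856 across genes (the mean log ratio at 0.396 and 0.0845), yet between features of a gene it was at r = 0.172 for different accessions and 0.345 for the same accession. The mean log ratio was at 0.228 and 0.520, with overlapping intervals for different accessions (0.132 to 0.210 for dye, 0.189 to 0.267 for the mean) and separate ones for the same accession (0.317 to 0.372 and 0.489 to 0.546), so this stays open. The other reading, columns of Hy5 over Cy3 with a large treatment effect, stays open too. It would not give a CHD6 value below 0 in all columns, but only 1 of 3 CHD6 features showed that, and CHD6 was itself used to choose the direction.

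The second pattern is the shift of 4 gene lists, for which dye bias stays open: a dye bias of equal size cancels in the mean only if every column is siRNA over control, and under Hy5 over Cy3 the mean as deposited would itself be dye bias. For p53 and NF-kappaB targets, the smaller of the shifts in both orientations was 0.148 and 0.0719, which speaks against an unequal dye bias only under the first reading. That 1 array carries the p53 shift as deposited is argued against under either reading, since leaving out 1 array brought it no lower than 0.141. Under the first reading, dye bias of unequal size over all genes would leave 0.00034 in the histone mean, against 0.108 with a standard error of 0.031 within orientations, and 0.00045 in the ribosomal mean, against 0.101 with a standard error of 0.085; the ribosomal call rests on replicate 4. These standard errors leave out the difference between orientations. Over all 4 arrays the SD of the shift was 0.158 for histone genes and 0.243 for ribosomal proteins. The slope used was 0.0026 over all genes, so the product is near 0 and cannot detect a bias of the list itself. A dye bias particular to a list or to signal strength, an effect of CHD6 loss, an off-target effect of this siRNA and a difference in transfection were not tested.

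The third pattern is HPRT1, as low as the CHD6 feature. It was at -0.63 in the orientation nearer 0 and -1.63 in the other, which speaks against dye bias of its probe alone only if every column is siRNA over control. Under the other reading, -1.13 could be dye bias of the probe, so this stays open. The treatment difference would then be -0.50, with limma adjusted p = 0.387 with the intercept alone. With dye orientation in the fit it would pass as a decrease (limma adjusted p = 0.00302), but so would 8219 of 18334 genes in either direction. Passing there does not single out HPRT1. A fault of 1 printed spot is argued against, since 10 of 10 features had a mean below -0.5; these share 1 transcript accession and may carry 1 probe sequence, which was not used here. A CHD6-dependent change and an off-target effect of the siRNA, whose sequence was not used here, stay open and untested.

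The 4 arrays have 8 sign patterns, too few for a share under 0.05. With the intercept alone the real pattern called 0 genes, so 8 of 8 patterns had to call as many, and this comparison decides nothing. The highest other, which follows the dye, called 7700, the same count as with the arrays turned by dye. With the dye coefficient, the real pattern called 4 genes, and 1 of the 7 patterns that could be fitted, the real one, called as many, with 0 as the highest other. For gene lists, 2 of 8 patterns called as many as the real one, which called 4, and the highest other also called 4.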

How the results depend on the processing

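Turning by dye, single features with the dye coefficient, and all alternatives to the dye fit were chosen after seeing the data; the causes of changes were not tested unless stated. CHD6 stayed below 0 in all settings run, at -0.20 with the median of its features, -0.10 on turning and -0.38 to -0.50 on leaving out 1 replicate. It passed within 1 orientation, where dye and treatment coincide, at -0.54 in the Hy5 arrays (feature 27564 at -1.32) and -0.35 in the Cy3 arrays (feature 27564 at -0.99), and feature 27564 passed with the dye coefficient (-1.15). Feature 1672 changed sign on turning (0.015) and, without replicate 2, reached 0.0033 (range -0.043 to 0.0033). Feature 36130 was at -0.027 without replicate 4. Genes called were 0 in the other settings, but 4 with the dye coefficient, 3713 in the Hy5 arrays, 5697 in the Cy3 arrays and 7700 on turning. The 4 genes of the dye fit became 7 with centring, robust moderation or array weights, 8 with medians per gene, 9 with scaling and 11 at a threshold of 0.1. Their calls were lost on leaving out 1 replicate. That leaves 1 array in 1 orientation, so the loss cannot be told from lower power. Tested as single features with the dye coefficient, 9 features passed, 7 of them of HPRT1, 1 of CHD6 and 1 unnamed, and none of GEMIN2, HSPA6 or ITM2C. The HPRT1 features may carry 1 probe sequence and so may not be separate calls. Quantile normalization called 4, 3 of them shared (HSPA6 adjusted p = 0.0965), and no moderation called 6, 0 of them shared.

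Lists called went from 4 to 2 in the Cy3 arrays and on turning, 8 for single features with the dye coefficient, 0 with an estimated correlation, 0 by fry, which tests a list against no change, and 2 to 11 on leaving out 1 replicate. The p53, NF-kappaB, histone and ribosomal lists no longer passed, in that order at adjusted p-values of 0.352, 0.411, 0.704 and 0.759 with an estimated correlation, and 0.0911, 0.217, 0.869 and 0.869 by fry. With the dye coefficient, these 4 lists passed camera at the preset correlation (adjusted p = 2.77e-06, 0.0166, 9.38e-05 and 0.00053). In that fit too, none of them passed with an estimated correlation (adjusted p from 0.587 to 0.720) or by fry (0.274 to 0.576). The p53 and NF-kappaB lists lost their calls in the Hy5 arrays (0.660 for both) and the Cy3 arrays (0.262 and 0.618), where only 2 arrays were fitted, and leaned lower on turning (0.869 and 0.873). The histone and ribosomal lists leaned lower in the Cy3 arrays (0.943 and 0.665) and were at 0.555 and 0.267 on turning. The ribosomal list was at 0.0787 with medians per gene and 0.0761 with array weights. Leaving out 1 replicate gave 0.000449 to 0.00560 for p53, 0.0162 to 0.0723 for NF-kappaB, 6.56e-06 to 0.104 for histones and 0.00193 to 0.768 for ribosomal proteins.

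The dye coefficient called 16860 single features and 4656 to 6814 genes on leaving out 1 replicate. Opposite-dye arrays correlated at -0.766 on average by Pearson, -0.664 by Spearman and -0.507 over the 10% of features with the largest means, and same-dye arrays at 0.793 and 0.700 by Spearman. The 36 named genes other than CHD6 kept their direction in 612 of 612 values that did not turn the arrays. This count was largely fixed in advance and is no check of these genes. Most were chosen for 1 sign on all 4 arrays, which leaving out arrays cannot reverse. Several settings, such as the dye coefficient and the moderation, do not alter the mean. On turning, 19 changed sign: ATR 0.033, CXCL3 -0.019, DNAAF4 0.010, FAS -0.157, GBE1 -0.038, GEMIN2 0.315, GHITM -0.298, H3-3B 0.075, IARS2 0.193, ITM2C 0.415, KICS2 0.270, MYCBP 0.273, REG1A -0.020, RNF4BP 0.288, RPL14 -0.112, STMND1 -0.120, SUMF1 -0.020, TCEAL7 -0.251 and TTPAL -0.0063. The filter for genes measured on all 4 arrays removed none. Lists have no value under robust moderation, no moderation or the fold filter, which camera does not use. Signal over background is unknown. Each log ratio is already the difference within a pair of samples on 1 array, so the fits are paired by design and no separate pairing was run.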

Other observations

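Some members of lists that were not called passed when adjusted over the list alone in the fit with the dye coefficient. None passed over all genes. The adjustment was made within each list and not across the 28 lists. In that fit 1717 of all 18334 genes (9.37%) had an unadjusted limma p under 0.05, so single members past a list's threshold are weak evidence. Of the YAP/TEAD targets, 3 did, all higher: CCN1, a matricellular protein (0.43 ± 0.09, SD, n = 4), AMOTL2 (0.38 ± 0.21, SD, n = 4) and AJUBA (0.28 ± 0.59, SD, n = 4), the last below 0 in the Hy5 orientation and at 0.067 without replicate 3. The CCN1 value averages 4 features with means from -0.035 to 0.635. Of the WNT targets, 3 did, all higher: CD44, a hyaluronan receptor (0.29 ± 0.07, SD, n = 4), the WNT inhibitor DKK1 (0.32 ± 0.11, SD, n = 4) and SP8 (0.44 ± 0.71, SD, n = 4), the last below 0 on replicates 2 and 4 and at 0.22 without replicate 1. Of the stress response genes, 3 did, all higher: DDIT3, the transcription factor CHOP (0.37 ± 0.12, SD, n = 4), TRIB3 (0.30 ± 0.67, SD, n = 4) and NUPR1 (0.35 ± 0.52, SD, n = 4). TRIB3 and NUPR1 were below 0 on replicates 1 and 3, and at 0.09 and 0.13 without replicate 2. DDIT3, CD44, DKK1, CCN1 and AMOTL2 were above 0 on all 4 arrays. With the intercept alone, 0 members of these 3 lists passed over the list alone. Directions in this part, including the next paragraph, are those of the columns as deposited, a likely but not settled reading. Values turned by dye are not given in this part.

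On the lower side, ATR (-0.44 ± 0.04, SD, n = 4) passed over the DNA repair list alone, the proliferation marker MKI67 (-0.46 ± 0.24, SD, n = 4) over the mitosis list alone and the interferon-induced gene IFIT1 (-0.37 ± 0.43, SD, n = 4) over its list alone, all with the dye coefficient. IFIT1 was above 0 on replicate 2, at 0.05, and at -0.22 without replicate 1. AKR1B10, an aldo-keto reductase among the NRF2 targets, was at 0.46 ± 0.27 (SD, n = 4), BAZ1A, an ISWI complex subunit, at 0.37 ± 0.49 (SD, n = 4) and GAP43, a growth cone protein, at 0.58 ± 0.37 (SD, n = 4), each past its list's threshold in that fit. BAZ1A was below 0 on replicate 4, at -0.17, and at 0.21 without replicate 3.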
